A study of Arabidopsis thaliana with 6 samples.

How the data were processed

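Total RNA from whole Arabidopsis thaliana seedlings was hybridised as biotin-labelled cRNA to Affymetrix ATH1 arrays, per the labels. The 6 arrays held 3 samples of the wild-type accession Ws and 3 of the ged1 mutant, with 6.6 µg of RNA used for each. All seedlings had spent 5 days in darkness and then 2 days under a 16-h photoperiod at 22 °C. The labels call the samples biological replicates and do not say whether they came from separate dishes or days. P-values therefore set the difference between the groups against the variation between these samples alone. Groups were taken from the genotype given in the labels.

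The deposited values were linear signal intensities, 1 per probe set. On each of the 6 arrays the mean intensity of the deposited values, without the lowest and highest 2%, was 100, so each array had been scaled to a common level. The summary algorithm, the background correction and the detection calls were not given in the sources used here. The deposited scaling was therefore kept. Median intensities ran from 31.5 to 50.3, with the highest on wild type replicate 3. The number of arrays limits the precision, and signals carry no read depth.

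Of 22810 probe sets, 64 were controls and 22746 were tested. The probe annotation gave 1 gene for 13513 of these, several genes for 503 and none for 8730. Of the 13513, 13436 were matched to the TAIR10.1 gene table, and no gene was named from a probe set with several. Probe sets not listed in the annotation are unnamed here, which leaves out many well-known genes, so only 111 of the 451 loci on the fixed gene lists had a probe set of their own. The gene mutated in ged1 is not named by the labels, and no targeted gene was checked.

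Intensities were analysed as log2(intensity + 16) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, 2-sided. P-values were adjusted by Benjamini-Hochberg over all 22746 probe sets, and an adjusted p under 0.05 was called. Fold changes on this scale understate changes of dim probe sets. The 27 Bacillus control probe sets, whose transcripts no plant makes, gave the background, and their highest intensity on an array (5.46 to 11.9) was taken as its limit. A probe set at or under that limit on all 3 arrays of a group was treated as not above background. Its change is given as "at least N-fold", the mean log2 intensity of the brighter group minus the mean log2 limit of the dimmer group's arrays. Between 77.8% and 88.5% of probe sets exceeded the limit per array.

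The 27 gene lists were fixed by locus before the data were examined. They covered seed storage proteins, oleosins and oil body proteins, late embryogenesis abundant (LEA) proteins, other dry-seed markers, seed maturation regulators, abscisic acid (ABA) signalling, ABA metabolism, ABA and cold responsive genes, gibberellin, light-harvesting proteins, nuclear photosystem genes, Calvin cycle enzymes, tetrapyrrole biosynthesis, plastid-encoded photosynthesis genes, plastid-encoded gene expression genes, nuclear plastid ribosomal proteins, light signalling, the circadian clock, flavonoids, lipid mobilisation, dark-induced genes, oxidative stress, heat shock, defence, root markers, shoot markers and the mitotic cell cycle. Each gene was represented by its brightest probe set. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 7 lists tested, while 17 lists with 1 to 4 measured members were described and 3 had no measured member. The clustering of called genes along the chromosomes was tested with 100000 permutations of the called genes, 1-sided, taking the highest count in any window of 100 neighbouring measured genes.

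The genes named were set by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among called probe sets with 1 gene and no overlap between the groups' arrays, the 3 members with the smallest p of each list, and 10 genes of greening and seed maturation, of which PORB alone had a named probe set. Genes outside it are said to have been chosen after their values were seen.

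The fit was tested on simulated data with 200 changed probe sets among 22746, in which it recovered 100% of 4-fold, 52.2% of 2-fold and 10.4% of 1.5-fold changes, with 8 false calls among 116. The changed probe sets were drawn from outside the dimmest 40%, and the simulated noise was independent with equal spread in both groups. In the deposited data the median SD of log2 values was 0.269 in wild type and 0.156 in ged1, so these rates may not hold there. Alternatives were quantile normalisation, median centring, pseudocounts of 1 and 64, leaving out the dimmest 20% or 40% of probe sets, the replicate number as a block, eBayes without a trend, array weights, a minimum change of 1.5-fold, each array left out in turn, the mean of a gene's probe sets, an estimated inter-gene correlation, the rotation test fry, other windows and a stricter threshold. Figures were drawn with matplotlib 3.10.9.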

Results

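Transcript levels were measured in seedlings of the Arabidopsis accession Ws and of ged1, a mutant named for greening after extended darkness. Seedlings of both genotypes were collected after 5 days of darkness followed by 2 days of light, and each genotype was represented by 3 arrays. The labels describe the wild-type seedlings as green and the ged1 seedlings as pale. That entry is at odds with the name of the mutant and was not verified here, and groups follow the genotype entry. The ged1 arrays resembled each other closely (Pearson r across probe sets from 0.983 to 0.987), whereas the wild-type arrays varied more (0.924 to 0.965). Wild type replicate 1 was less like wild type replicate 3 (0.924) than like each ged1 array (0.932 to 0.943). Wild type replicate 3 had the highest median intensity, 50.3 against 31.5 to 36.7 on the other 5 arrays, and the lowest 5′/3′ intensity ratios of the GAPDH (0.460), actin (0.416) and ubiquitin (0.381) controls.

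The first comparison asked which transcripts differed between ged1 and wild type. Of the 10 largest falls, 4 were members of the fixed seed lists, namely AT3G15670, PAP85, M17 and LEA18. The largest fall was outside these lists. LCR67, a small cysteine-rich defensin, had an intensity of 2868 ± 647 (SD, n = 3) in wild type and 5.21 ± 2.06 in ged1, which was not above background and gave a level at least 395-fold lower. The LEA genes AT3G15670, M17 and LEA18, whose products accumulate in desiccating embryos, were at least 228-fold, 202-fold and 151-fold lower. PAP85, a vicilin-like storage protein, had an intensity of 2266 ± 619 in wild type and 8.60 ± 5.23 in ged1.

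The other genes among the 10 largest falls were AT1G54870, the papain-type cysteine protease gene AT3G54940, the LEA-family gene AT3G02480, the dehydrin gene listed as LEA, and AT5G66780. LEA was at least 126-fold lower, and the log2 changes of the other 4 lay between -6.39 for AT1G54870 and -5.55 for AT5G66780. All 10 falls had limma adjusted p-values from 9.13e-07 for LCR67 to 7.98e-05 for AT5G66780.

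Among the 10 largest rises, AT3G29970 went from 22.3 ± 15.2 (SD, n = 3) in wild type to 1770 ± 167 in ged1, a log2 change of 5.62 ± 0.26 (SE, limma adjusted p = 1.11e-05). AT2G17850, a rhodanese-like gene, rose by 4.39 on the log2 scale and CML38, which encodes a calmodulin-like calcium sensor, by 3.92. AT4G39675 rose from 123 ± 42.2 to 1837 ± 91.2. AT3G03270, a universal stress protein gene, rose from 235 ± 51.2 to 2330.4 ± 188. AT1G33055, the wound-responsive family genes AT4G10270 and AT4G33560, and the RING finger gene AT5G42200 rose by 3.27, 3.14, 2.74 and 2.36 on the log2 scale. EXO, which promotes cell expansion in response to brassinosteroids, rose by 2.38 ± 0.37 (SE, limma adjusted p = 0.00796), and its call was lost without ged1 replicate 3 (adjusted p = 0.0520).

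**Figure D1:**
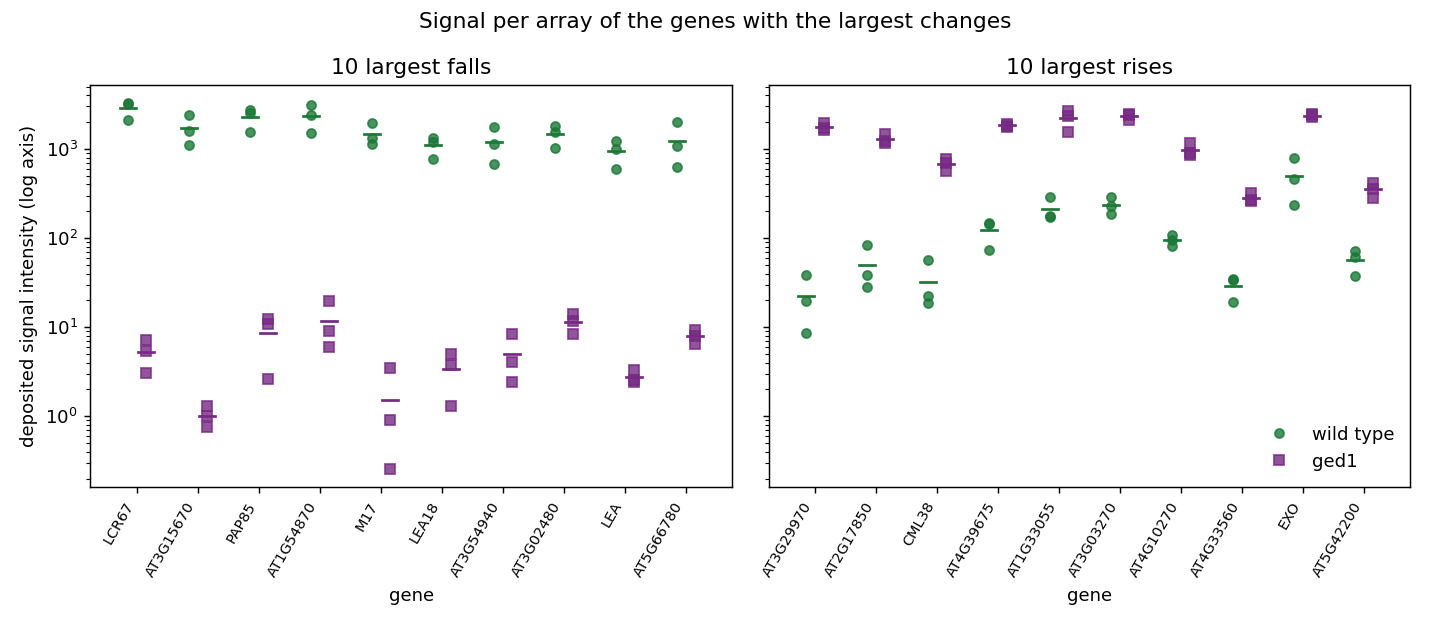
Deposited signal intensity (log axis) of the 10 genes with the largest falls and the 10 with the largest rises in ged1. Each point is 1 array, with circles for wild type and squares for ged1, and bars are group means. For LCR67 the means were 2868 and 5.21, and for AT3G29970 they were 22.3 and 1770. The rule that chose the 20 genes required a called probe set with 1 gene and no overlap between the groups, so unnamed probe sets are left out.

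In all, 1779 of 22746 probe sets were called, with 854 higher and 925 lower in ged1, and 867 of them had 1 gene. Falls were larger than rises. Among called probe sets, 61 fell by at least 16-fold on the log2(intensity + 16) scale and 3 rose by as much, while 517 fell and 264 rose by at least 2-fold. Of the probe sets called lower, 98 were not above background on any ged1 array, and of those called higher, 3 were not above background on any wild-type array. The median log2 change over all probe sets was -0.10 with the deposited scaling and 0.03 after quantile normalisation, and with arrays centred on their medians the split became 973 higher and 564 lower. The number of calls depended on the arrays and the variance model, being 2953 without wild type replicate 1, 668, 524 and 576 without ged1 replicate 1, 2 and 3, 6780 with array weights and 296 against a minimum change of 1.5-fold.

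The second comparison asked which of the fixed gene lists shifted between the genotypes. Of 29 measured members of the seed storage, oleosin and LEA lists, 23 fell, none rose and 6 did not pass, and 16 were not above background on any ged1 array. The published account of ged1 reports such transcripts from these samples, so these 3 lists are not independent evidence of their direction.

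Of 5 measured seed storage protein genes, 4 fell, with the same 4 adjusted over the list alone and a median log2 change of -3.41 (-4.73 with genes not above background at their bound). PAP85 was joined by the cupins AT2G28490, with an intensity of 1179 ± 356 (SD, n = 3) in wild type and a log2 change of -5.47, and AT4G36700, at least 26.5-fold lower. The list as a whole was lower by camera (adjusted p = 4.41e-08), and with an estimated correlation its adjusted p was 0.131. All 4 measured oleosin genes, which coat oil bodies, fell, also adjusted over the list alone. AT3G01570 and OLEO3 had log2 changes of -5.02 and -2.70, and AT2G25890 was at least 39-fold lower.

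Of 20 measured LEA genes, 15 fell, and 17 fell adjusted over the list alone, with a median log2 change of -3.21 (-4.15 with genes at their bound). The 3 with the smallest p were M17, LEA18 and AT3G15670. The list was lower by camera (adjusted p = 1.38e-21, and adjusted p = 0.131 with an estimated correlation). The 5 members that did not pass, named after their values were seen, were AT5G27980 and the cold- or drought-induced genes COR47, COR15A, COR15B and LTI30. COR47 had an intensity of 1288 ± 513 (SD, n = 3) in wild type and 1666 ± 311 in ged1. LTI30 (log2 change -0.63) and AT5G27980 (-0.42) passed adjusted over the list alone. AT5G27980 and COR15A had mean intensities of 8.75 and 8.21 in wild type, within the range of the background limits, which left little room for a fall.

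Regulators and markers of other seed functions were few among the named probe sets. EEL, a bZIP factor that acts in late embryogenesis, fell by 1.17 on the log2 scale (limma adjusted p = 0.0125), and BZIP53, a bZIP activator of seed maturation genes, rose by 0.64 (limma adjusted p = 0.0415). Each call was lost in 4 of the 6 fits that left out 1 array, that of EEL (limma adjusted p up to 0.0676) without wild type replicate 2 or any 1 of the ged1 arrays, and that of BZIP53 (limma adjusted p up to 0.188) without wild type replicate 2 or 3 or ged1 replicate 1 or 2. The BZIP53 call was also lost with quantile normalisation, a replicate block, no intensity trend, a pseudocount of 64 and a minimum change of 1.5-fold. Among genes that mobilise seed oil, ICL, SDP1 and AIM1 did not pass, and ICL, an enzyme of the glyoxylate cycle, had intensities of 3925 ± 770 (SD, n = 3) in wild type and 2983 ± 239 in ged1. SDP1, an oil body lipase, passed adjusted over the list alone (log2 change 0.66).

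Among 8 measured tetrapyrrole genes, 1 fell, both over all probe sets and adjusted over the list alone. It was PORB, a light-dependent protochlorophyllide oxidoreductase of chlorophyll synthesis, which went from 397 ± 153 (SD, n = 3) in wild type to 56.0 ± 11.1 in ged1 (limma adjusted p = 9.26e-04). CHLM and CHLI2, enzymes of the magnesium branch of chlorophyll synthesis, had log2 changes of 0.34 and -0.21 and did not pass. The list was not called by camera (adjusted p = 0.523).

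No measured nuclear gene of the photosynthetic apparatus passed in limma, over all probe sets or adjusted over the list alone, and PRK alone had an unadjusted p under 0.05. Only 5 of 32 photosystem and electron transport loci, 3 of 21 light-harvesting loci and 3 of 18 Calvin cycle loci were measured. The other loci of these lists stay undecided. The 5 photosystem and electron transport genes had log2 changes from 0.12 to 0.53, with 0.53 for ATPC1, 0.31 for PSAN and 0.36 for PSBY (camera adjusted p = 0.0955). This list was called higher without wild type replicate 2 (adjusted p = 0.0232) and with no intensity trend, and over all alternatives its adjusted p ran from 0.0232 to 0.777. LHCB4.1, LHCB4.2 and LHCB4.3, which encode a minor antenna protein, had log2 changes of 0.31, 0.37 and 0.02. The Calvin cycle genes PRK, SBPASE and RCA had log2 changes of 0.63, 0.31 and 0.35. The plastid ribosomal protein genes AT1G64510, AT2G43030 and AT5G65220 had log2 changes of 0.37, 0.19 and 0.11.

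None of the 23 plastid-encoded photosynthesis genes passed, over all probe sets or adjusted over the list alone, and their median log2 change was -0.18 against an upward camera direction (adjusted p = 0.866), which was downward with quantile normalisation and with median centring. psbA, which encodes the D1 protein of photosystem II, had an intensity of 895 ± 835 (SD, n = 3) in wild type and 125 ± 54.7 in ged1, and was the only member with an unadjusted p under 0.05 (limma adjusted p = 0.0631). It was called in 6 of 16 alternatives. atpE had a log2 change of -0.82. The 7 plastid-encoded gene expression genes likewise held no call (camera adjusted p = 0.625), with matK at -0.49, accD at 0.37 and rpoC1 at 0.30. The median intensity of the 23 genes was 208, 779 and 1591 on the 3 wild-type arrays, the highest on replicate 3, and 480, 757 and 687 on the ged1 arrays. The photosynthesis list was called lower by camera without wild type replicate 1 (adjusted p = 0.00324) and higher without wild type replicate 3 (adjusted p = 0.0498). Without wild type replicate 3 the plastid gene expression list and the tetrapyrrole list were also called by camera (adjusted p = 0.0498 for each). Their median log2 changes in that fit differed in sign, at 0.91 for plastid gene expression and -0.23 for tetrapyrrole genes.

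**Figure D2:**
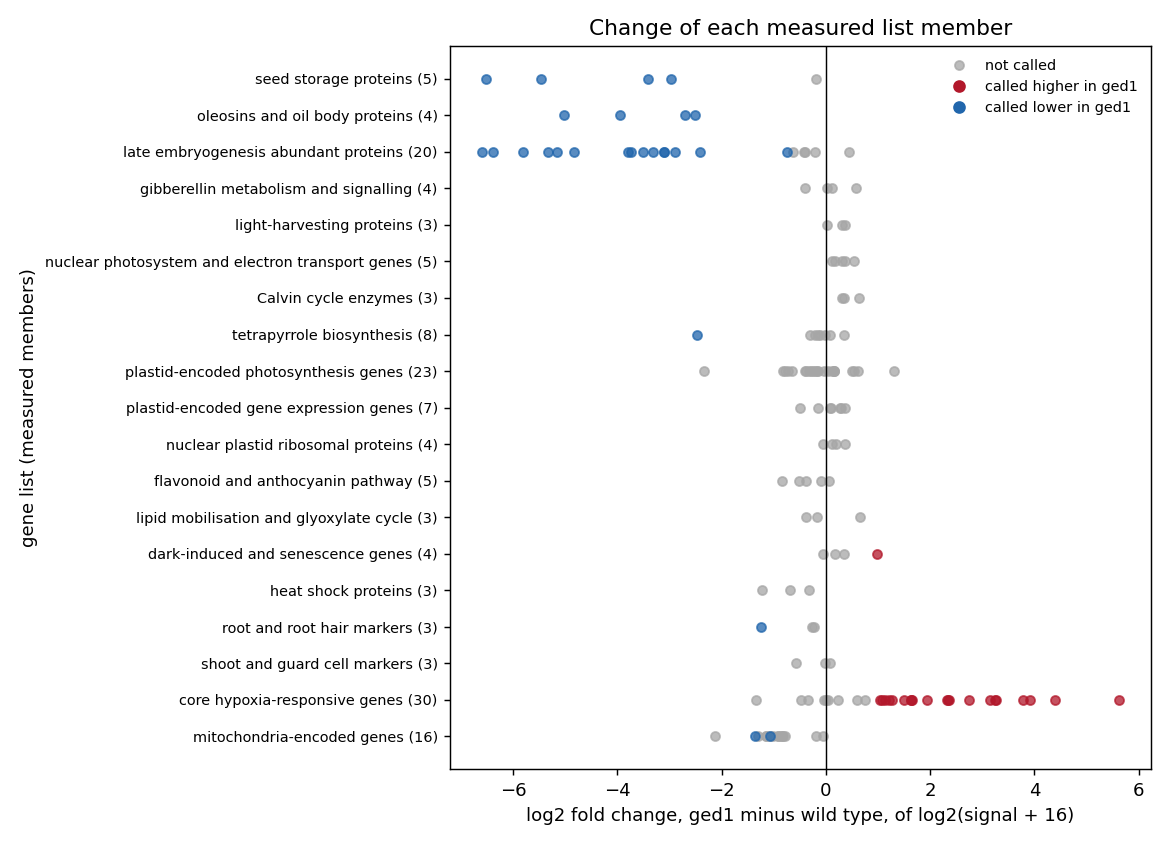
Log2 fold change (ged1 minus wild type, of log2(intensity + 16)) of each measured member of the lists with 3 or more measured members. Points are genes, coloured by their call. The seed storage, oleosin and LEA lists hold 23 falls among 29 measured members. The lists of nuclear photosynthesis genes hold no call, but few of their loci were measured.

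The remaining lists held few calls. MCCA, which acts in leucine breakdown and is induced by darkness, rose by 0.99 on the log2 scale (limma adjusted p = 0.0207), while the related genes ETFQO and IVD had log2 changes of 0.34 and 0.18. PYK10, a beta-glucosidase of root endoplasmic reticulum bodies, went from 3782 ± 404 (SD, n = 3) in wild type to 1596 ± 184 in ged1 (limma adjusted p = 0.00775), while the root hair expansins EXPA7 and EXPA18 had log2 changes of -0.26 and -0.24. The MCCA call was lost without any 1 of the ged1 arrays and without wild type replicate 3 (limma adjusted p up to 0.0944). The PYK10 call was lost without ged1 replicate 2 or 3 (limma adjusted p up to 0.0717) and with median centring (limma adjusted p = 0.0620).

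None of the 5 flavonoid genes passed (camera adjusted p = 0.317), and DFR and AT4G14090 passed adjusted over the list alone. DFR had a log2 change of -0.84 and AT5MAT of -0.38, and AT4G14090 was at least 1.09-fold lower. Of the gibberellin genes, GID1A, a gibberellin receptor, passed adjusted over the list alone (log2 change 0.57), and GID1B and GID1C had log2 changes of -0.40 and 0.12. The clock gene GI passed as the only measured member of its list (log2 change 0.51) and not over all probe sets (limma adjusted p = 0.0854). HYH of light signalling (0.49), STZ of oxidative stress (-0.19), PDF1.2 of defence (-0.19), the heat shock genes ATHSP22.0 (-1.22) and AT1G53540 (-0.32), and the shoot and guard cell genes CLV3 (-0.58), YAB3 (0.08) and FMA (-0.02) did not pass. The heat shock list had a mean log2 value of 9.14 on wild type replicate 1, and 6.82 and 6.28 on wild type replicates 2 and 3. STZ had 8.94, 7.02 and 7.10 on these arrays. Without wild type replicate 1 the median log2 change of the heat shock list was 0.25. The list of ABA and cold responsive genes was measured by 1 probe set with several genes, which did not pass, and those of ABA signalling, ABA metabolism and the mitotic cell cycle held no measured member.

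The third comparison asked whether called genes clustered along the chromosomes. Among 13264 measured nuclear genes, 861 were called, with shares from 5.78% on chromosome 4 to 7.03% on chromosome 1. The highest count in any window of 100 neighbouring measured genes was 15, first reached on chromosome 1 between AT1G27410 and AT1G29700. The median highest count by chance was also 15 (permutation test, 1-sided, p = 0.771), so no clustering was detected.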

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

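The 2 called lists and their direction held in all alternatives with enough members except with an estimated inter-gene correlation, where camera called 0 lists (2 at an unadjusted p under 0.05, and 2 by fry) and the adjusted p was 0.131 for both seed storage and LEA proteins. Leaving out the dimmest 40% of probe sets left 1 list called, since the seed storage list then had under 5 members. Counts of calls moved more. The total was 6780 (3087 higher, 3693 lower) with array weights and 296 (70 higher, 226 lower) against a minimum change of 1.5-fold, and median centring left 564 lower. The cause was not tested for any of these. Without 1 array, totals ran from 524 to 2953, with 195 to 1361 higher and 329 to 1592 lower, and the number of lists called from 2 to 5. Of the 668, 524 and 576 calls without a ged1 array, 661, 524 and 572 were among the 1779. The plastid-encoded photosynthesis list, not called with all arrays, had adjusted p-values from 0.00324 to 0.851 without 1 array, and its upward direction was downward without wild type replicate 1 or ged1 replicate 2, with quantile normalisation, median centring, a replicate block or array weights, without the dimmest 20% or 40% and by fry. With the replicate number as a block, 1157 probe sets were called, 512 of them higher and 645 lower. Deviations of same-numbered arrays correlated at 0.27, -0.11 and -0.03, and 2 of the 6 arrays were closest to their own number, so the numbers were not taken to pair the samples. The chromosome permutation test did not pass with windows of 50 or 200 genes (p = 0.818 and 0.415) or at an adjusted p under 0.01 (p = 0.570). Of 32 called genes and probe sets followed by name, 25 kept their call in every alternative run, and 7 (EXO, EEL, BZIP53, MCCA, PYK10, cox1 and cox2) lost it in at least 1. The 32 had been named for large changes or the smallest p of their list in the same data. Their stability therefore does not stand for that of the 1779 calls. The sign of the log2 change held in every alternative run for these 32. Of 45 not called, 17 were called in at least 1, and the sign of 13 changed in at least 1, for 6 of them (the ABA and cold responsive probe set, LHCB4.3, AIM1, STZ, PDF1.2 and FMA) with quantile normalisation or median centring. Signals near the Bacillus controls limit 16 of the 29 seed genes to bounds in ged1.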

Other observations

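The gene groups of this part and the tests of explanations were chosen after values had been seen, whereas the alternative settings were planned. Genes known to be induced by low oxygen in many cell types were among the largest rises, and a list of such genes was then written. Of its 30 measured members, 21 rose in ged1, but 15 of these had been seen among the rises before. Adjusted over the list alone, 22 were higher and 1 was lower, AT1G05575 (log2 change -1.34). Over all probe sets no member was called lower, while 1 was without wild type replicate 1 or 2, with a pseudocount of 1 and without the dimmest 20% or 40%. AT4G27450 rose from 1219 to 3857 in mean intensity, AT3G10040, a trihelix transcription factor gene, from 17.1 to 110, and PDC2, a pyruvate decarboxylase of ethanol fermentation, from 50.9 to 147. Members that did not pass included AT3G10020 (log2 change -0.04) and FHL (0.00).

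Of the 4 vacuolar processing enzymes, proteases that mature vacuolar proteins, those called differed in direction. BETA-VPE, the main form in seeds, fell by 3.30 on the log2 scale and DELTA-VPE, known from the seed coat, by 1.68. GAMMA-VPE, a vegetative form, rose by 1.01. ALPHA-VPE did not pass (log2 change -0.19), and its sign changed with quantile normalisation and with median centring. The GAMMA-VPE call was lost without wild type replicate 2 or any 1 of the ged1 arrays (limma adjusted p up to 0.0922). Of 11 measured GSTU glutathione transferases, GSTU25, GSTU20 and GSTU22 fell by 1.91, 1.79 and 1.31, and GSTU18 rose by 0.99. SWEET11, SWEET16 and SWEET17, which transport sugars, rose by 1.13, 0.97 and 0.77 among 14 measured SWEET genes. The calls of the 3 SWEET genes were lost without ged1 replicate 2 or 3 (limma adjusted p up to 0.0706). Of 41 families tested by shared symbol, the UGT glycosyltransferases alone passed, with 8 of 47 measured members lower (Fisher's exact test, adjusted p = 0.0168). With quantile normalisation 4 of the 47 were lower (unadjusted p = 0.0902), with median centring 3 and with array weights 21. The number lower was 10, 2 and 3 without wild type replicate 1, 2 and 3 in turn, and 1, 0 and 0 without ged1 replicate 1, 2 and 3.

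PAP85, AT3G15670 and M17 of the seed lists, with mean intensities of 2266, 1707 and 1479 in wild type, had 8.60, 1.02 and 1.54 in ged1, while COR47 of the LEA list had 1288 and 1666. Leaving out any 1 wild-type array kept at least 22 of the 23 called members of the seed lists, which argues against a single array as the source. Other scalings left a median log2 change of -3.11 or lower, which argues against the scaling. A candidate explanation that stays open is a share of ungerminated seeds among the wild-type seedlings, since 23 of 29 members fell together and the labels give no germination counts. A difference in how the 2 genotypes shut down the seed programme stays open as well and was not tested.

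The rise of hypoxia genes could have come from filling the list with genes already seen among the rises. Of the 15 members not seen before the list was written, 6 rose, against 2.81% of other genes (Fisher's exact test, p = 2.07e-06), which argues against that. Lower oxygen around the ged1 seedlings and an effect of the mutation cannot be told apart, since the labels give no oxygen level and the 6 rises among the 15 members not seen before bear on both alike.

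Transcripts encoded in the mitochondria had a median log2 change of -0.97 over 16 genes, of which cox1 and cox2 passed and lost their calls in 3 and 5 of the 6 fits without 1 array (limma adjusted p up to 0.0772 and 0.114). The list was lower by camera (adjusted p = 3.30e-04), also without each array in turn, wild type replicate 3 included (adjusted p from 2.34e-06 to 8.64e-04). It was not called with an estimated correlation (adjusted p = 0.35) or by fry (adjusted p = 0.138). These p-values were adjusted over this list and the hypoxia list alone, not with the fixed lists. Both lists were written after values had been seen, so the p-values are no independent test of the fall. The median intensity of the 16 genes was 25.8, 51.9 and 166 on the 3 wild-type arrays and 22.4 to 26.1 on the ged1 arrays. Without wild type replicate 3 the median change was -0.33, consistent with that array carrying most of the size of the difference. That array also had the lowest GAPDH 5′/3′ ratio (0.460), and lower RNA integrity cannot be told apart from a difference between the seedlings with 1 such array. Mean 5′/3′ ratios were also lower in wild type than in ged1, for GAPDH (0.613 against 0.664), actin (0.488 against 0.629) and ubiquitin (0.460 against 0.574). Single arrays overlapped, with GAPDH at 0.818 on wild type replicate 1, the highest of all arrays, and 0.520 on ged1 replicate 1. Whether RNA integrity contributed to the differences between the groups was not tested.

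The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, called 1779 probe sets and the highest of the others 0, where up to 1557 had an unadjusted p under 0.05 in limma against 4944 in the real one. For lists, the real split called 2 and the highest of the others 6, and 8 of the 10 splits called at least 2. The 3 splits that set wild type replicates 1 and 2 with a ged1 array against the rest called 4 to 6 lists, with 175 to 828 probe sets at an unadjusted p under 0.05. The 3 that set wild type replicate 1 with 2 ged1 arrays against the rest called 2 to 4 lists, with 480 to 1557 such probe sets, and the 3 that set wild type replicates 1 and 3 with a ged1 array against the rest called 1 to 2, with 227 to 364. The number of lists called thus did not set the real split apart from the others. What gave the list calls in the other splits was not tested.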
